A study of Homo sapiens with 32 samples.

How the data were processed

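The series holds RNA sequencing of CD4 T cells, the helper class of T lymphocytes, taken from the blood of healthy donors and of donors with psoriasis. Per the labels, the cells were isolated by negative selection from blood mononuclear cells, activated through the T cell receptor and kept with vehicle or with 0.5 mM nicotinamide riboside (NR), a precursor of the coenzyme NAD. Total RNA was extracted with a column kit for small samples, and stranded total RNA libraries were sequenced on an Illumina HiSeq instrument, per the labels. There were 4 groups of 8 libraries, 32 in all. Each library's group and number came from its title.

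The authors deposited a single table of raw read counts per gene, with 23374 gene rows and 1 column for each of the 32 libraries. Per the submitters' processing notes, FastQC, Trimmomatic, STAR and featureCounts were used with the GRCh38 genome, and the versions of these tools and the annotation release were not given in the sources used here. A further column of the table equalled, in all 23374 rows, the number of libraries with at least 2 counts, and its smallest value was 16, so genes seen in fewer libraries were not analysed here. The table listed the Y copies of 30 pseudoautosomal genes beside their X copies, and 25 of these had identical counts in all 32 libraries. Reads that match several places therefore appear to have been counted at each, so values of paralogs, pseudogenes and repeated small RNA genes are uncertain.

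Total counts per library ranged from 8.86 to 67.3 M (M for mega), with a median of 42.1 M. Gene identifiers without their version were matched to symbols for 23242 of 23344 rows, leaving aside the Y copies, and 22989 were in GENCODE release 29 (GRCh38), from which coordinates were taken. The 30 Y copies and 43 rows of Y-linked genes, XIST and TSIX were left out of all tests, leaving 23301 rows.

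Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16's quasi-likelihood F test, with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15) and robust dispersion estimation. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05, and all tests were two-sided. The NR comparisons used 1 fit to all 32 libraries in 4 groups. From this fit came the NR effect in healthy donors, the NR effect in psoriasis donors, the mean of both effects and their difference. The 2 donor groups were compared in separate fits of the 16 vehicle and of the 16 NR libraries. The labels do not say which libraries share a donor, and the design fixed before the data were examined added a term for neighbouring title numbers only if all 16 such pairs passed a similarity check. That condition was not met, so the NR fit had no pairing term. If vehicle and NR libraries do share donors, they are not independent samples, and an unpaired test then has less power. Effects are log2 fold changes with their standard errors (SE), and CPM values are counts per M after TMM scaling, given as mean ± SD. Values of log2 CPM per library used a prior count of 2.

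The 25 gene lists were fixed before the data were examined. They covered TH17, TH1, TH2 and regulatory T cells, naive and memory T cells, T cell activation, NF-kB targets, interferon-stimulated genes, the arginine, urea cycle and polyamine genes, and NRF2 targets. They also covered other antioxidant enzymes, NAD metabolism, the ATF4 and amino acid response, glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, cholesterol biosynthesis, the cell cycle, replication-dependent histones, and heat shock and immediate early genes. The last 5 lists were markers of monocytes, B cells, NK cells, CD8 T cells, and platelets and erythroid cells. Each was tested with camera from limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 25 lists. The test was repeated with an estimated correlation and with fry. Members that passed were counted over all genes tested and adjusted over the list alone.

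The genes named were chosen by a rule written before the data were examined. It took up to 10 genes in each direction with the largest change among those past the threshold and at a mean of at least 1 CPM, which for NR comparisons had also moved the called way in at least 75% of the pairs concerned. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It added up to 4 members with the smallest p from each list described and, for NR, a fixed set of cytokine, arginine, NRF2 and NAD genes. HLA genes, immunoglobulin and T cell receptor segments, genes with common deletion alleles and unnamed identifiers were excluded from the parts that rank genes. TXNRD1, which the rule names in other fits, is also plotted.

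Alternatives set before the data were examined were RLE size factors, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, a replicate block, the pair as a random effect, fits of each donor group alone or of all libraries together, 1 surrogate variable from sva 3.50.0, and leaving out each pair or library. Fits without 4 libraries that did not resemble the library with the neighbouring number, and fits of the 14 remaining pairs, were added after seeing the data.

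The fits were tested on simulated counts with the real library sizes and gene means. Among 67 genes changed 2-fold, edgeR recovered 68.7% for NR in healthy donors, 71.6% in psoriasis donors and 85.1% over both (19468 genes). Between donor groups it recovered 52.2% in vehicle cells (17739 genes) and 71.6% in NR cells (17919 genes). At 1.5-fold these shares were 26.9%, 35.8%, 53.7%, 22.4% and 14.9%. The simulated genes varied independently of each other, unlike real genes. Simulated vehicle and NR libraries of these fits shared no donors, while the real ones may. These shares therefore need not hold for the real data. Raising the 23 glycolysis genes 1.2-fold in simulated counts passed the list test, and 0 of the 24 other lists did.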

Results

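RNA was sequenced from activated human CD4 T cells of healthy donors and of donors with psoriasis, an inflammatory skin disease, each kept with vehicle or with 0.5 mM NR. There were 8 libraries in each of the 4 groups, numbered by their titles. Total counts were 40.9 ± 16.7 M in healthy vehicle libraries, 45.8 ± 11.8 M in healthy NR, 36.1 ± 14.8 M in psoriasis vehicle and 43.6 ± 12.5 M in psoriasis NR (mean ± SD, n = 8 each). The lowest total, 8.86 M, was in the healthy vehicle group. The study's title sets NR against TH17 inflammation, arginine synthesis and redox control, so genes of these systems are described for each NR comparison. Coordinates are those of GRCh38.

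In healthy donors, NRF2 target genes, which encode antioxidant and detoxifying enzymes, were higher with NR as a list. Of 32 measured members 25 had positive values, with a median log2 fold change of 0.15 (camera with preset correlation, adjusted p = 0.000271). This list did not pass with an estimated correlation (adjusted p = 0.990). HMOX1, the heme-degrading enzyme heme oxygenase 1, stood at 27.2 ± 38.1 CPM with vehicle and 59.7 ± 68.6 CPM with NR (n = 8 each), a log2 fold change of 1.15 (SE 1.11). GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis, stood at 26.5 ± 16.5 and 40.9 ± 26.2 CPM, a log2 fold change of 0.63 (SE 0.41). NQO1, a quinone reductase, had a value of 0.70 (SE 0.56) and KEAP1, the inhibitor of NRF2, 0.22 (SE 0.17). NFE2L2, which encodes NRF2 itself, was at 0.06 (SE 0.17) and GCLC, the catalytic partner of GCLM, at 0.16 (SE 0.27). None of these genes passed alone in this fit without a pairing term, and 0 of the 32 members passed adjusted over the list alone. If vehicle and NR libraries share donors, these errors include the spread between donors. A fit with a pairing term, chosen after seeing the data, called members of this list in healthy donors and is given below.

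The TH17 list in healthy donors had a median of 0.04 over 21 measured members, 13 of them positive (adjusted p = 0.750). IL17A, the leading TH17 cytokine, was at 10.3 ± 9.19 CPM with vehicle and 10.3 ± 6.99 CPM with NR (n = 8 each), a log2 fold change of -0.0030 (SE 0.74). IL17F was at -0.56 (SE 0.73) and IL22 at -0.03 (SE 0.80). IFNG, the TH1 cytokine, was at 0.08 (SE 0.85). The TH2 cytokines IL4, IL5 and IL13 were at 0.06 (SE 0.65), 0.03 (SE 0.79) and -0.10 (SE 0.58). IL10 was at 0.02 (SE 0.43), and FOXP3, the regulatory T cell transcription factor, at 0.08 (SE 0.40). The arginine, urea cycle and polyamine list had a median of 0.05 (16 of 21 positive, adjusted p = 0.750). In it, ASL, which releases arginine from argininosuccinate, was at -0.01 (SE 0.21) and ARG2, the mitochondrial arginase, at 0.16 (SE 0.36). ASS1, the enzyme before ASL, lay under the filter on counts and was not tested. NMRK1, the kinase that phosphorylates NR, was at -0.02 (SE 0.23), and NAMPT, which starts NAD salvage from nicotinamide, at 0.06 (SE 0.61).

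Over all 19788 genes tested in healthy donors, edgeR called 0 changed by NR, with 35 higher and 47 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0 (99 and 108 genes at an unadjusted p under 0.05). The genes with the smallest p that were higher were HAR1B (1.45, SE 0.48), CCDC96 (0.56, SE 0.20), ZSWIM8-AS1 (1.09, SE 0.42), CDRT4 (1.01, SE 0.39) and SNRPGP10 (0.42, SE 0.17). Those that were lower were RAB11B-AS1 (-0.42, SE 0.17), BANF1P2 (-1.04, SE 0.42), BMPR1AP2 (-0.73, SE 0.29), ADH5P4 (-0.57, SE 0.23) and HNRNPCL1 (-0.78, SE 0.32). None of the 10 passed, and several are pseudogenes or low in counts. The biological coefficient of variation of this fit, which had no pairing term, was 48.3%. Far fewer genes reached an unadjusted p under 0.05 than chance alone gives among 19788, so the test was strict. Its count of 0 therefore does not show that NR changed no gene.

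In psoriasis donors, NRF2 targets were again higher with NR as a list, and cell cycle genes were lower. These and 2 lists of mitochondrial genes passed with the preset correlation only (adjusted p = 0.960 for each with an estimated correlation). For NRF2 targets 28 of 32 members were positive, with a median log2 fold change of 0.28 (adjusted p = 0.00751, camera with preset correlation). HMOX1 stood at 45.6 ± 51.5 CPM with vehicle and 137 ± 182 CPM with NR (n = 8 each), a log2 fold change of 1.59 (SE 1.11). GCLM stood at 36.5 ± 17.2 and 66.1 ± 45.5 CPM, a log2 fold change of 0.86 (SE 0.41) with an unadjusted p of 0.0437 in edgeR. NQO1 was at 0.80 (SE 0.55), KEAP1 at 0.30 (SE 0.17), PRDX1, a peroxiredoxin, at 0.28 (SE 0.17), GCLC at 0.29 (SE 0.27) and NFE2L2 at 0.15 (SE 0.17). Of 35 cell cycle genes 29 were negative, with a median of -0.25 (adjusted p = 0.000115). The mitotic kinase PLK1 was at -0.45 (SE 0.18), the centromere histone CENPA at -0.98 (SE 0.54) and cyclin CCNB2 at -0.62 (SE 0.37), while PCNA, the replication clamp, was at 0.23 (SE 0.11). The 13 mitochondrially encoded mRNAs had a median of 0.09 with 12 positive (adjusted p = 0.00751), among them MT-ND1 at 0.14 (SE 0.09) and MT-ND5 at 0.16 (SE 0.11). The nuclear-encoded respiratory chain had a median of 0.05 with 36 of 48 positive (adjusted p = 0.00751). In that list NDUFC2 was at 0.29 (SE 0.18) and NDUFV1, also of complex I, at -0.20 (SE 0.09). None of the members of these 4 lists passed over all genes or adjusted over the list alone.

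**Figure D1:**
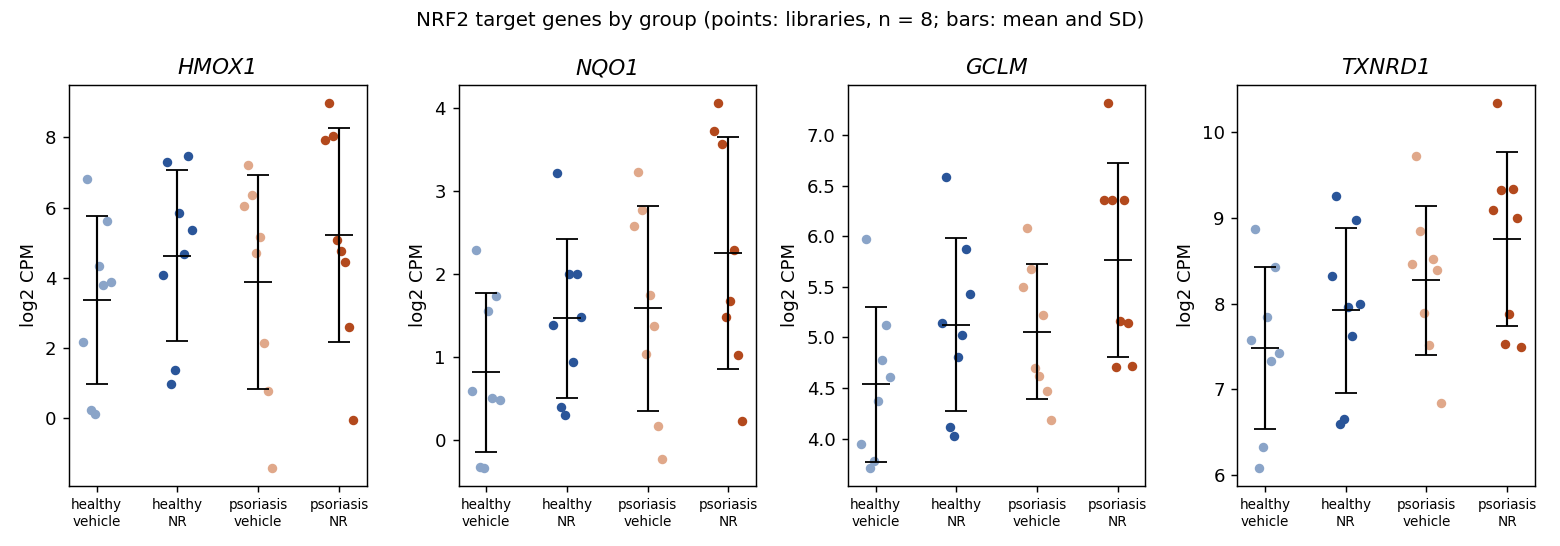
Expression of 4 NRF2 target genes as log2 CPM on the vertical axis, with 1 point for each library of the 4 groups on the horizontal axis (n = 8) and bars for mean and SD. The NR groups had the higher mean for each gene, as for HMOX1 at 4.63 against 3.37 in healthy and 5.22 against 3.88 in psoriasis donors, and the SD between libraries of a group was 2.39 to 3.04 for HMOX1.

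Cytokine and arginine genes in psoriasis donors did not pass. The TH17 list had a median of -0.04 with 8 of 21 members positive (adjusted p = 0.393, with camera's direction up, against the sign of the median). IL17A was at 7.08 ± 8.93 CPM with vehicle and 5.86 ± 7.23 CPM with NR (n = 8 each), a log2 fold change of -0.26 (SE 0.74). IL17F was at -0.06 (SE 0.74) and IL22 at -1.01 (SE 0.81). IFNG was at 0.07 (SE 0.86), IL4 at -0.31 (SE 0.65), IL5 at -0.70 (SE 0.79), IL13 at -0.88 (SE 0.58), IL10 at -0.43 (SE 0.44) and FOXP3 at -0.26 (SE 0.40). The signs of IL17A, IL4, IL5, FOXP3 and the TH17 median were the opposite in the 14 matching pairs described below. Those pairs leave out vehicle replicate 35, which had the highest TH17 (4.85) and regulatory T cell (6.32) scores among psoriasis vehicle libraries. These negative values thus depend on the libraries used. The arginine, urea cycle and polyamine list had a median of 0.04 with 12 of 21 positive (adjusted p = 0.891), while its mean was -0.0069. NOS3, endothelial nitric oxide synthase, was at -0.87 (SE 0.40), ASL at -0.06 (SE 0.21) and ARG2 at 0.16 (SE 0.36). NMRK1 was at -0.09 (SE 0.23) and NAMPT at -0.0018 (SE 0.61).

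Of the 19788 genes tested, edgeR called 0 changed by NR in psoriasis donors in the fit without a pairing term. At an unadjusted p under 0.05 there were 128 higher and 165 lower genes, far fewer than chance alone gives. DESeq2 and limma-voom called 0 (343 and 262 at an unadjusted p under 0.05). Some fits with a pairing term did call genes and are given with the alternatives below. The highest-ranked genes that were higher were LBR, the lamin B receptor (0.31, SE 0.09), MRPL36P1 (0.99, SE 0.29), CHRNA6 (1.01, SE 0.31), the histone demethylase KDM6A (0.19, SE 0.07) and the histone chaperone ASF1A (0.35, SE 0.13). Those that were lower were CSAD, of taurine synthesis (-0.29, SE 0.09), CCDC17 (-0.54, SE 0.17), SENP3-EIF4A1 (-1.22, SE 0.39), LIN7B (-0.54, SE 0.18) and LMNTD2-AS1 (-0.84, SE 0.29). None of the 10 passed.

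Over both donor groups, NR went with higher NRF2 targets, mitochondrially encoded mRNAs, respiratory chain genes and ATF4 targets as lists, and with lower cell cycle genes. These 5 lists passed with the preset correlation only (adjusted p = 0.999 for each with an estimated correlation). NRF2 targets had a median of 0.20 with 28 of 32 positive and the cell cycle list a median of -0.17 with 27 of 35 negative (adjusted p = 0.000114 for each, camera with preset correlation). GCLM was at 0.74 (SE 0.29), KEAP1 at 0.26 (SE 0.12), NQO1 at 0.75 (SE 0.39), PRDX1 at 0.23 (SE 0.12), HMOX1 at 1.37 (SE 0.79), GCLC at 0.23 (SE 0.19) and NFE2L2 at 0.11 (SE 0.12). In the cell cycle list PLK1 was at -0.22 (SE 0.13), MKI67, a proliferation marker, at -0.41 (SE 0.27) and TPX2, a spindle protein, at -0.29 (SE 0.20), while PCNA was at 0.13 (SE 0.08). All 13 mitochondrial mRNAs were positive, with a median of 0.07 (adjusted p = 0.00118), and 38 of 48 respiratory chain genes, with a median of 0.03 (adjusted p = 0.0209). The ATF4 and amino acid response had a median of 0.08 with 28 of 32 positive (adjusted p = 0.0217), with the amino acid transporter SLC38A2 at 0.20 (SE 0.11) and the tRNA exporter XPOT at 0.17 (SE 0.11).

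The other 20 lists did not pass over both donor groups. Medians were 0.03 for TH17 cells (adjusted p = 0.309), 0.04 for TH1 cells (0.752), -0.07 for TH2 cells (0.752), -0.02 for regulatory T cells (0.752), 0.02 for naive and memory T cells (0.752) and 0.04 for T cell activation (0.655). NF-kB targets had a median of 0.01 (adjusted p = 0.836), interferon-stimulated genes -0.05 (0.181), heat shock and immediate early genes 0.06 (0.0912) and replication-dependent histones, with 3 measured members, -0.04 (0.996). Among metabolic lists, the medians were 0.06 for arginine, urea cycle and polyamine genes (adjusted p = 0.752), 0.02 for other antioxidant enzymes (0.655), -0.01 for NAD metabolism (0.234), 0.05 for glycolysis (0.162) and -0.01 for cholesterol biosynthesis (0.946). Markers of other cells had medians of -0.02 for monocytes (adjusted p = 0.752), 0.05 for B cells (0.996), 0.14 for NK cells (0.752), 0.10 for CD8 T cells (0.996) and 0.11 for platelets and erythroid cells (0.942). For 6 of the 25 lists the median, the mean and the direction of the test were not all of 1 sign, and each of these 6 was far from the threshold.

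**Figure D2:**
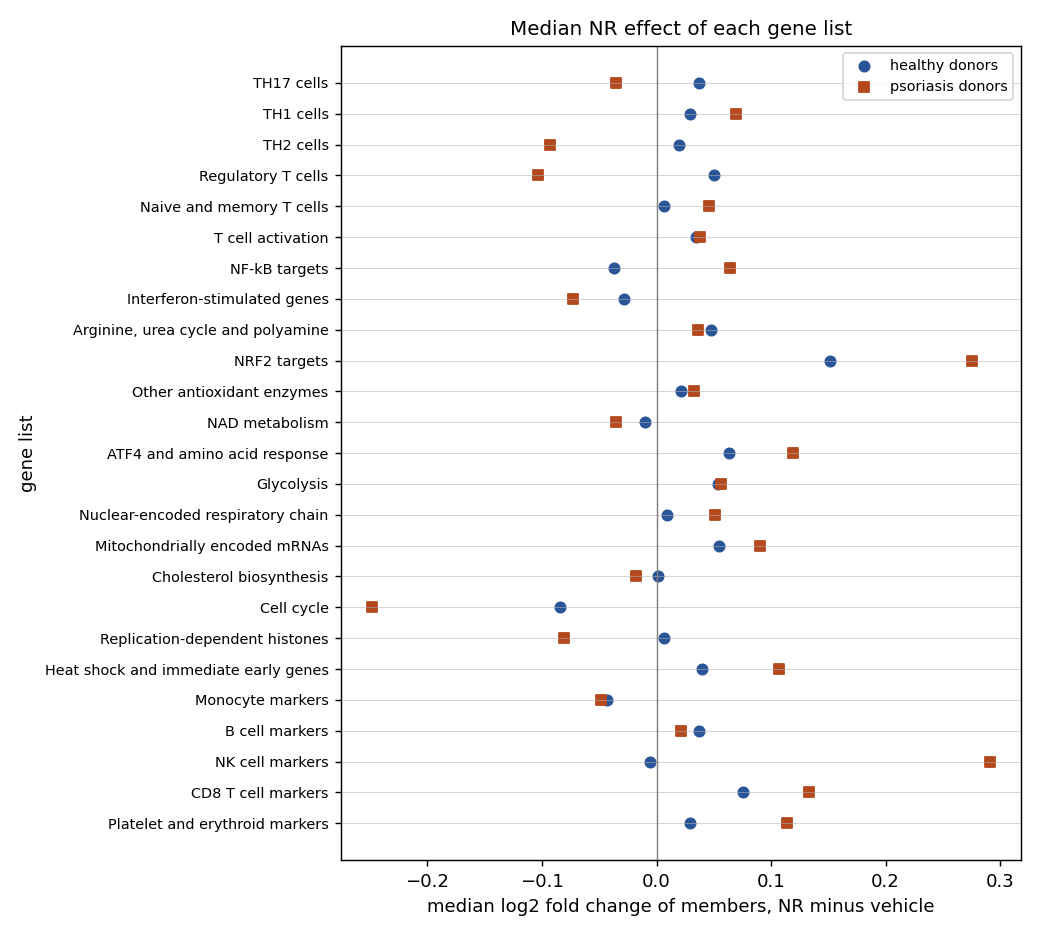
Median log2 fold change of each gene list's members, NR minus vehicle, on the horizontal axis, with 1 circle for healthy and 1 square for psoriasis donors in each of the 25 lists on the vertical axis. NRF2 targets lie at 0.15 and 0.28 and the cell cycle list at -0.08 and -0.25.

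At the level of single genes, edgeR called 0 of 19788 genes over both donor groups in the fit without a pairing term, which has less power if libraries share donors, with 142 higher and 141 lower at an unadjusted p under 0.05. DESeq2 and limma-voom called 0 as well, with 323 and 241 at an unadjusted p under 0.05. All these counts are below what chance alone gives at that p, so 0 calls do not show that NR changed no gene. LBR was the highest-ranked gene (0.25, SE 0.06), followed among higher genes by ZKSCAN5 (0.17, SE 0.05), the proteasome subunit PSMA3 (0.26, SE 0.08), ASF1A (0.28, SE 0.09) and CHRNA6 (0.65, SE 0.22). The lower genes with the smallest p were small or repeated RNA genes and a pseudogene, namely RNVU1-7 (-1.46, SE 0.43), HNRNPA1P52 (-2.11, SE 0.63), 5_8S_rRNA (-1.23, SE 0.37), RNA5-8SN2 (-1.23, SE 0.37) and RNA5-8SN3 (-1.23, SE 0.37), whose reads may be shared between copies. Of the cytokine genes, IL17A was at -0.13 (SE 0.52), IL17F at -0.31 (SE 0.52), IL22 at -0.52 (SE 0.57), IFNG at 0.07 (SE 0.60), IL4 at -0.13 (SE 0.46), IL5 at -0.34 (SE 0.56), IL13 at -0.49 (SE 0.41) and IL10 at -0.21 (SE 0.31). FOXP3 was at -0.09 (SE 0.28), ASL at -0.03 (SE 0.15), ARG2 at 0.16 (SE 0.25), NMRK1 at -0.06 (SE 0.16) and NAMPT at 0.03 (SE 0.43). None of the genes in this paragraph passed.

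Whether NR acted differently in psoriasis than in healthy donors was tested as the difference of the 2 effects. HMOX1 differed by 0.44 (SE 1.54), GCLM by 0.22 (SE 0.57), NQO1 by 0.10 (SE 0.79), GCLC by 0.13 (SE 0.38) and NFE2L2 by 0.09 (SE 0.23). Each difference was smaller than its error in this fit without a pairing term. If vehicle and NR libraries share donors, these errors include the spread between donors, so they cannot show that the effects were alike. For cytokines the values were -0.26 (SE 1.05) for IL17A, 0.50 (SE 1.04) for IL17F, -0.98 (SE 1.14) for IL22, -0.01 (SE 1.21) for IFNG, -0.37 (SE 0.91) for IL4, -0.73 (SE 1.11) for IL5, -0.78 (SE 0.82) for IL13 and -0.45 (SE 0.61) for IL10. FOXP3 was at -0.34 (SE 0.57), ASL at -0.05 (SE 0.30), ARG2 at -0.01 (SE 0.51), NMRK1 at -0.08 (SE 0.33) and NAMPT at -0.07 (SE 0.86). No list passed, the cell cycle list coming closest with a median of -0.20 and 28 of 35 negative (adjusted p = 0.0944), and NRF2 targets had a median of 0.11 (adjusted p = 0.980, with camera's direction down). edgeR called 0 of 19788 genes, with 25 higher and 39 lower at an unadjusted p under 0.05, as did DESeq2 and limma-voom (81 and 87 at an unadjusted p under 0.05). Chance alone gives far more genes at that p, so 0 calls do not show that the 2 effects were alike. The genes with the smallest p were ADH5P4 (0.87, SE 0.33), PPIAP3 (2.08, SE 0.83), MORN2 (0.89, SE 0.36), TMEM14DP (1.15, SE 0.49) and MAPRE1P1 (1.48, SE 0.64) in the positive direction. In the negative direction they were ZSWIM8-AS1 (-1.90, SE 0.59), AMT, of glycine cleavage (-1.51, SE 0.54), SENP3-EIF4A1 (-1.53, SE 0.55), SYP (-0.77, SE 0.29) and CKLF-CMTM1 (-1.68, SE 0.64), and none of the 10 passed.

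Across genes, the NR effects in healthy and psoriasis donors correlated with Pearson's r of 0.152 and Spearman's rho of 0.236 over 19788 genes, which are not independent replicates. Among the 9091 genes with a mean of at least 10 CPM, r was 0.620 and rho 0.576, and 73.4% of genes had the same sign in both. The effects come from different libraries, so no control was shared. No gene was called in either group, so the overlap of calls could not be compared with chance.

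The vehicle libraries of psoriasis and healthy donors were compared to describe the donor groups without NR. Healthy libraries carried the numbers 2 to 24 and psoriasis libraries 26 to 48. Any handling that followed the numbering therefore cannot be told apart from disease, here or in NR cells, and the labels name no batches. Psoriasis cells had lower values of TH1, TH17, T cell activation and interferon-stimulated genes as lists, and higher values of NRF2, ATF4 and B cell genes. All 7 lists passed with the preset correlation only, with an adjusted p = 0.928 for each with an estimated correlation and 0 lists past the threshold with fry. Of 22 TH1 genes 21 were negative, with a median log2 fold change of -0.51 (adjusted p = 0.00347, camera with preset correlation). TNF, a cytokine, stood at 172 ± 104 CPM in psoriasis and 431 ± 234 CPM in healthy donors (n = 8 each), a log2 fold change of -1.32 (SE 0.39). IFNG was at -2.05 (SE 0.84), FASLG, the Fas ligand, at -0.78 (SE 0.31) and LTA, lymphotoxin alpha, at -0.60 (SE 0.28). The TH17 list had 15 of 21 negative and a median of -0.20 (adjusted p = 0.00699), with the cytokine CSF2 at -1.30 (SE 0.51), IL17F at -1.23 (SE 0.63), BATF at -0.74 (SE 0.38) and IL4I1 at -0.81 (SE 0.45). T cell activation genes had 17 of 22 negative and a median of -0.22 (adjusted p = 0.00347). In that list LAG3, an inhibitory receptor, was at -0.87 (SE 0.23), the only member called adjusted over the list alone (adjusted p = 0.0348), and was not called over all genes in edgeR (adjusted p = 0.433). Interferon-stimulated genes had 29 of 31 negative and a median of -0.24 (adjusted p = 0.00347), with OASL at -0.83 (SE 0.34), MX1 at -0.51 (SE 0.22) and ISG15 at -0.58 (SE 0.25).

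NRF2 targets were higher in psoriasis vehicle cells, with 26 of 31 positive and a median of 0.28 (adjusted p = 0.00699). In that list glutathione reductase GSR was at 0.71 (SE 0.21), NQO1 at 0.94 (SE 0.51) and the transporter ABCC1 at -0.24 (SE 0.13). The ATF4 and amino acid response had 27 of 32 positive and a median of 0.27 (adjusted p = 0.00139), with the serine synthesis enzyme PSAT1 at 1.23 (SE 0.54), MTHFD1L at 0.53 (SE 0.20), SHMT2 at 0.37 (SE 0.15) and XPOT at 0.43 (SE 0.15). All 10 B cell markers were positive with a median of 1.90 (adjusted p = 0.0455), among them FCRL1 at 2.13 (SE 0.84) and CD79B at 1.38 (SE 0.63). All 15 monocyte markers were also positive with a median of 0.65, without passing (adjusted p = 0.455), and PPBP, a platelet chemokine, was at 4.03 (SE 1.33), called adjusted over its list alone (adjusted p = 0.0241). Mean marker scores per library were higher in psoriasis for all 5 marker lists, by 0.103 for NK cells to 0.922 for platelets and erythroid cells. Exact permutation p-values lay between 0.260 and 0.941 (n = 8 each), so this test did not separate the donor groups. With the spread within groups it cannot show that they held other cells in like amounts. The scores varied widely within groups, with an SD for monocyte markers of 2.38 in psoriasis and 1.59 in healthy donors. The vehicle libraries lowest in monocyte score, healthy replicate 11 (1.18) and psoriasis replicate 47 (-0.06), were also lowest in NRF2 score (3.49 and 3.38). Those highest in it, healthy replicate 5 (5.73) and psoriasis replicate 32 (6.20), had NRF2 scores of 5.30 and 5.32. NRF2 levels thus cannot be assigned to CD4 T cells alone.

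Over all genes, edgeR called 1 of 18051 genes between donor groups in vehicle cells. This was RPL37P2, a processed pseudogene of ribosomal protein gene RPL37 (chromosome 11, 67682772 to 67683058), at 14.4 ± 2.66 CPM in psoriasis and 26.99 ± 3.27 CPM in healthy donors (n = 8 each), a log2 fold change of -0.90 (SE 0.12, adjusted p = 0.0145). At an unadjusted p under 0.05 there were 755 higher and 705 lower genes, against 42 genes called by DESeq2 and 2 by limma-voom. RPL37P2's adjusted p passed 0.05 without healthy replicate 2 (0.0573), healthy replicate 23 (0.0542) or psoriasis replicate 29 (0.0537), where its log2 fold change was -0.89, -0.89 and -0.89, within a range of 3.82e-09 to 0.0573 over all alternatives in edgeR, DESeq2 and limma-voom. The next genes did not pass: MDM2, the p53 ubiquitin ligase (0.50, SE 0.09, adjusted p = 0.142 in edgeR), its relative MDM4 (0.45, SE 0.10), NUDT3 (0.46, SE 0.09), RBM27 (0.52, SE 0.10) and the connexin GJB6 (1.36, SE 0.29) were higher. RPS19P7 (-1.52, SE 0.26), RNF5P1 (-1.67, SE 0.31), ANXA2R (-0.53, SE 0.11), the Notch glycosyltransferase LFNG (-0.57, SE 0.12) and C11orf68 (-0.40, SE 0.08) were lower.

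**Figure D3:**
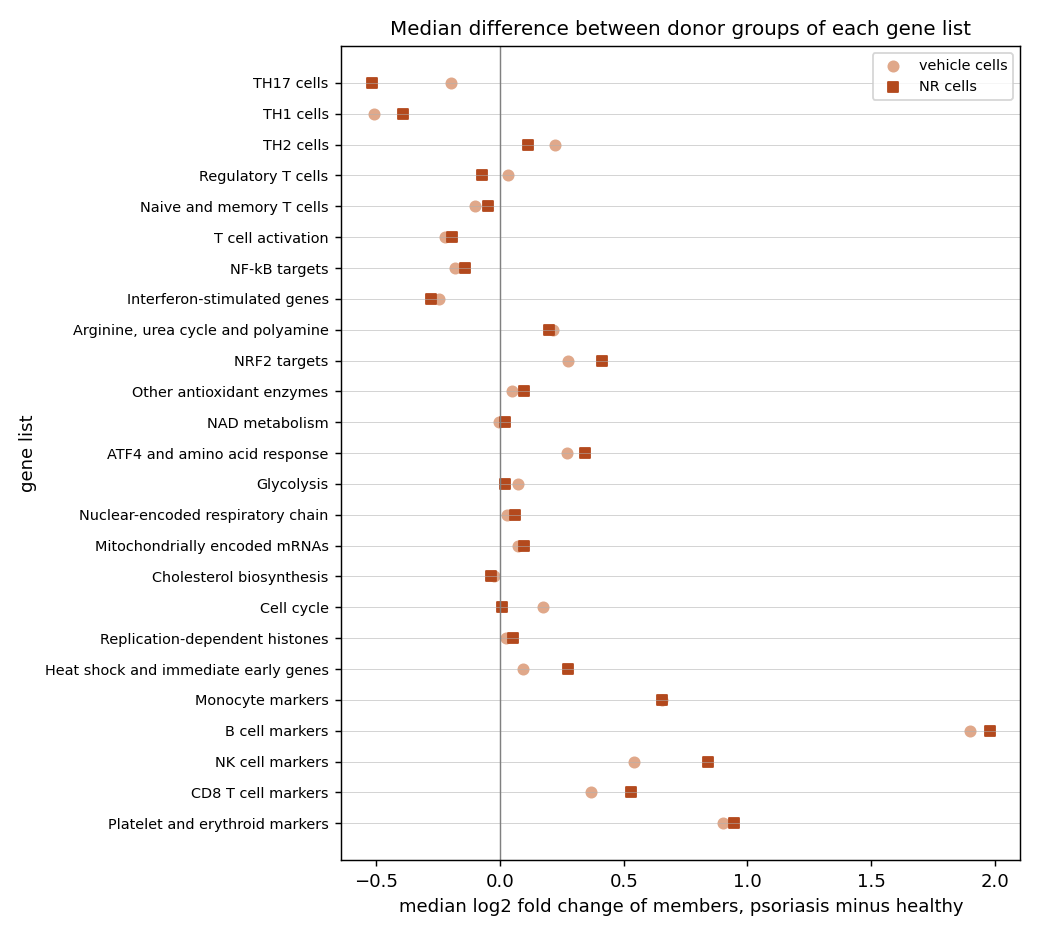
Median log2 fold change of each gene list's members, psoriasis minus healthy, on the horizontal axis, with 1 circle for vehicle and 1 square for NR cells in each of the 25 lists on the vertical axis. B cell markers lie at 1.90 and 1.98 and TH1 genes at -0.51 and -0.39.

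In NR cells the donor groups differed in many of the lists that passed in vehicle cells, from libraries that are not independent of the vehicle libraries if they share donors. The 6 lists that passed did so with the preset correlation only, with an adjusted p = 0.838 for each with an estimated correlation and 0 lists past the threshold with fry. TH1 genes had 19 of 22 negative and a median of -0.39, and TH17 genes 15 of 21 negative and a median of -0.52 (adjusted p = 0.0300 for each, camera with preset correlation). TNF was at -1.39 (SE 0.40), IFNG at -2.04 (SE 0.89), CSF2 at -1.26 (SE 0.50) and BATF at -0.73 (SE 0.28). T cell activation genes had 17 of 22 negative and a median of -0.19 (adjusted p = 0.00934), and interferon-stimulated genes 30 of 32 negative and a median of -0.28 (adjusted p = 0.00118), with MX1 at -0.59 (SE 0.22). LAG3 was at -0.99 (SE 0.19), called adjusted over the list alone (adjusted p = 0.00191) and not over all genes in edgeR (0.162). Higher lists were NRF2 targets, with 27 of 31 positive and a median of 0.41 (adjusted p = 0.0300), and the ATF4 and amino acid response, with 28 of 32 positive and a median of 0.34 (adjusted p = 0.000183). GSR was at 0.81 (SE 0.26), TXNRD1, thioredoxin reductase, at 0.87 (SE 0.47), PSAT1 at 1.34 (SE 0.50) and TRIB3 at 0.90 (SE 0.37). B cell markers were all positive with a median of 1.98 (adjusted p = 0.106) and all 15 monocyte markers with a median of 0.66 (adjusted p = 0.922).

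Among 18300 genes tested in NR cells, edgeR again called RPL37P2 and no other gene, at 15.2 ± 2.66 CPM in psoriasis and 26.7 ± 3.19 CPM in healthy donors (n = 8 each), a log2 fold change of -0.82 (SE 0.12, adjusted p = 0.0337). At an unadjusted p under 0.05 there were 967 higher and 967 lower genes, and DESeq2 called 50 and limma-voom 5. The call was lost without any 1 of healthy replicates 6 (adjusted p = 0.0986), 9 (0.0760), 12 (0.115) and 21 (0.0915) or psoriasis replicates 27 (0.0775), 30 (0.111), 33 (0.0774), 39 (0.0522) and 45 (0.110), and without 4 libraries that did not resemble the library with the neighbouring number (0.113), with log2 fold changes for RPL37P2 between -0.78 and -0.87. Over all alternatives the adjusted p ranged from 1.13e-07 to 0.115. Higher genes that did not pass were HPRT1, of purine salvage (0.64, SE 0.13), SHLD2 (0.49, SE 0.10), RESF1 (0.59, SE 0.13), NIN (0.36, SE 0.08) and CYP4V2 (1.31, SE 0.30). Lower genes that did not pass were the pseudogenes RPS19P7 (-1.39, SE 0.23), RPL26P6 (-0.90, SE 0.15) and RPS15P4 (-0.57, SE 0.11), and KLC4 (-0.47, SE 0.09).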

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

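The test of HSPA6 used a fit chosen after seeing which pairs of libraries matched, and the other values followed rules set before. IL4 in psoriasis NR replicate 30 stood at a log2 CPM of 3.826, away from the other 7 libraries of its group, which lay between -0.578 and 1.045. IL5 in healthy NR replicate 24 stood at -2.482, below the others of its group, which lay between -0.160 and 1.498. These were 2 of 108 groups of 8 libraries examined, where chance alone gives about 1 in 20, or 5.4, so no pattern was read from them.

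HSPA6, an inducible heat shock protein, was raised by NR more in psoriasis than in healthy donors over the 14 matching pairs, by 1.773 on the log2 scale (SE 0.25, adjusted p = 0.0229, edgeR), a difference between groups that passed its test. Its adjusted p ranged from 1.54e-07 to 1 over the alternatives. Reads can be shared with its near-identical copy HSPA7, which differed by 0.97 (SE 0.27) and did not pass, so the gene behind the value is uncertain. In the block of all 16 numbered pairs the HSPA6 difference was 1.26 and was not called. The call was lost without healthy pair 2-3 (adjusted p = 0.0729), 8-9 (0.0823), 14-15 (0.0999), 17-18 (0.0705) or 20-21 (0.0876), and without psoriasis pair 26-27 (0.0633), 29-30 (0.0505), 32-33 (0.173), 41-42 (0.0611), 44-45 (0.0612) or 47-48 (0.0703), with differences for HSPA6 between 1.649 and 1.851 in these fits. Of 100 splits of the pairs, only the real one called a gene, with 1 against a highest other count of 0.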

How the results depend on the processing

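Fits without the 4 unmatched libraries and fits of the 14 matching pairs were chosen after the results were seen, and all other alternatives were set before the data were examined. In the fit of all 32 libraries without pairing, all 4 NR counts stayed at 0 with RLE size factors, no filter, a mean of at least 10 CPM, DESeq2, limma-voom, leaving out any pair, and leaving out the 4 unmatched libraries. RLE moved the median of all genes by at most 0.0051, and the sign of a list median changed only for NK cell markers in healthy donors, a list that did not pass. Among single named genes and settings, 27532 values kept their side of the threshold, of which 483 that passed in neither fit changed sign. A further 218 passed it only in the alternative and 607 only as reported, and no value that passed in either fit changed sign. The 27532 include the many values that passed in neither fit, since the fit without pairing called 0 genes for NR. That count therefore does not show that calls were stable. Depth limits genes with few counts, since the lowest library held 8.86 M.

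The labels name no donors, so pairing rests on title numbers. Deviations from the group mean correlated over the 16 numbered pairs with a lowest value of 0.0234, a median of 0.879 and a highest of 0.948 (14653 genes), and 28 of 32 libraries correlated best with their own number, a hint from the data and not from the design. The check set before the data were examined asked for over 0.1 in all 16, and 15 passed. With the block of all 16 pairs edgeR called 2 genes in psoriasis donors (AKR1C3 and GCLM), 8 over both groups (GCLM, NQO1, TXNRD1, AKR1C3, HMOX1 and LBR higher, SNORD3B-1 and MKI67 lower) and 0 for healthy donors and for the difference, with a coefficient of variation of 16.7% against 48.3%. With the pair as a random effect in limma-voom, 1 gene was called over both groups. The block passed 5 lists in healthy donors, 11 in psoriasis donors, 9 over both and 4 for the difference, against 1, 4, 5 and 0 without pairing. With an estimated correlation or with fry the unpaired counts of lists were 0 throughout. The cause was not tested.

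In the 14 matching pairs, 4 genes were called in healthy donors, 125 in psoriasis donors, 197 over both and 1 for the difference. In the same order, the counts were 2, 269, 331 and 0 at a mean of at least 10 CPM, 7, 716, 817 and 1 with DESeq2, 0, 2, 8 and 0 with all 16 pairs, 0, 0, 4 and 0 with the pair as a random effect, and 0, 0, 0 and 0 without a block. Each donor group's pairs alone gave 2 and 8. RLE size factors, no filter and limma-voom kept all counts within 1.5 times. Lists past the threshold numbered 6, 13, 12 and 8, against 1, 1, 1 and 0 with an estimated correlation, 1, 10, 11 and 0 with fry, and 1, 8, 7 and 1 without a block, while all 16 pairs gave 4 for the difference. The cause was not tested.

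Leaving out 1 of the 14 pairs gave 2 to 4 genes in healthy donors, with 2 without healthy pair 2-3, 5-6, 14-15 or 23-24. Psoriasis counts ranged from 8 to 405, with 78 without healthy pair 2-3, 21 without 20-21 and 64 without 23-24, and 14 without psoriasis pair 26-27, 14 without 29-30, 405 without 32-33, 8 without 41-42 and 49 without 44-45. Counts over both ranged from 40 to 479, with 60 without healthy pair 2-3, 129 without 5-6, 318 without 11-12, 63 without 20-21 and 88 without 23-24, and 67 without psoriasis pair 26-27, 60 without 29-30, 479 without 32-33 and 40 without 41-42. The difference gave 0 or 1, with 0 without healthy pair 2-3, 8-9, 14-15, 17-18 or 20-21, or psoriasis pair 26-27, 29-30, 32-33, 41-42, 44-45 or 47-48.

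Between donor groups, 1 gene was called in vehicle and 1 in NR cells. DESeq2 called 42 and 50, limma-voom 2 and 5, a fit of all 32 libraries 8 and 9, a surrogate variable 1 and 2, and fits without the 4 unmatched libraries 2 and 0. Leaving out 1 vehicle library gave 0 to 6 genes, with 0 without healthy replicate 2, healthy replicate 23 or psoriasis replicate 29, 2 without healthy replicate 14 or psoriasis replicate 41, and 6 without psoriasis replicate 35. Leaving out 1 NR library gave 0 to 3, with 0 without healthy replicate 6, 9, 12 or 21 or psoriasis replicate 27, 30, 33, 39 or 45, and 3 without psoriasis replicate 42. Lists past the threshold numbered 7 and 6, and 0 and 0 with an estimated correlation or with fry. The cause was not tested.

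The correlation of the NR effects was 0.152 over all genes without pairing, 0.620 at a mean of at least 10 CPM, 0.126 in the 14 pairs, and 0.597 in the 14 pairs at a mean of at least 10 CPM. Weakly expressed genes with large errors are left out at 10 CPM.

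In 100 splits without pairing, every split called at least the real count of 0, and the highest others were 139 in healthy donors, 1017 in psoriasis donors, 277 over both and 14 for the difference. The median of the other splits was 0, and 2, 7, 1 and 4 of them called any gene, in the same order. The cause of the large counts was not tested. Between donor groups, 4 of 100 splits in vehicle and 5 of 100 in NR cells called at least the real 1, with highest others of 1217 and 156. Whether chance explains these 2 counts of 1 gene is left open, since they lie on either side of a limit of 5 in 100 written after the data were seen. In the 14 pairs, 2 of 100 splits reached the real 4 in healthy donors (highest other 2160), 1 of 32 the real 125 in psoriasis donors (highest other 1) and 3 of 100 the real 197 over both (highest other 566). In psoriasis donors no other split came near 125, but 1 of 32 is the smallest share these splits allow. The pairs were also chosen after seeing the data, so chance is not excluded there. Chance is left open too for healthy donors and over both groups, where other splits called more genes than the real one.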

Other observations

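The fits of the 14 matching pairs and the tests below were chosen after the results were seen, and the pairs were picked by the similarity of their libraries, not by their NR response, which by itself lowers the residual spread (coefficient of variation 12.8%). In these pairs NR raised HMOX1, NQO1, GCLM and TXNRD1 in both donor groups, 4 NRF2 targets of heme breakdown, quinone reduction, glutathione synthesis and thioredoxin reduction. HMOX1 rose by 1.30 in healthy (SE 0.14, edgeR adjusted p = 0.000652) and by 1.87 in psoriasis donors (SE 0.16, adjusted p = 3.36e-05), and was higher in 14 of 14 pairs. TXNRD1 rose by 0.44 and 0.64, GCLM by 0.59 and 0.86 and NQO1 by 0.65 and 0.87. These 4 were all the genes called in healthy donors, and all 4 were among the 79 raised in psoriasis donors. Independent lists of independent genes would share 0.0158 genes in direction. Both effects came from 1 fit with shared dispersion estimates, and real genes do not vary independently, so that value does not measure chance here. In healthy donors HMOX1 and TXNRD1 stayed called without any 1 pair. GCLM was lost without healthy pair 2-3 (adjusted p = 0.0666), 5-6 (0.146), 14-15 (0.0558), 20-21 (0.138) or 23-24 (0.166), at a mean of at least 10 CPM (0.0530) and with the healthy pairs alone (0.0748), in a range of 9.98e-06 to 1 over all alternatives. Its log2 fold change stayed between 0.51 and 0.64 in all of them. NQO1 was lost without healthy pair 2-3 (0.144), 5-6 (0.169), 8-9 (0.0939), 11-12 (0.0854), 14-15 (0.0558), 17-18 (0.0558) or 23-24 (0.195) and psoriasis pair 29-30 (0.0770), 32-33 (0.0575) or 44-45 (0.0510), with limma-voom (0.152) and with the healthy pairs alone (0.485), in a range of 0.000625 to 1. The log2 fold change of NQO1 stayed between 0.59 and 0.72. None of the 4 was called in healthy donors with all 16 pairs, with the pair as a random effect or without a block, where HMOX1 was at 1.29, 1.29 and 1.16 and TXNRD1 at 0.44, 0.45 and 0.45. As a list, 33 NRF2 targets had medians of 0.15 in healthy and 0.34 in psoriasis donors, with 27 and 30 positive (adjusted p = 5.53e-20 and 2.77e-23). The list also passed with an estimated correlation (adjusted p = 0.0022 and 0.00137), with 4 and 12 members called over all genes and 11 and 17 adjusted over the list alone.

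In psoriasis donors of these pairs NR raised the heat shock gene HSPA6 (1.92), thioredoxin TXN (0.59), the aldo-keto reductase AKR1C3 (0.67), GCLC (0.34), the chemokine receptors CXCR6 (0.66) and CCR4 (0.47), and PNP (0.25), which can split NR. NR lowered MYBL1 (-0.51), KLF8 (-0.64), SCAI (-0.57), the proliferation marker MKI67 (-0.50) and PARP15 (-0.32), while the replication clamp PCNA rose (0.33). The calls of lower genes depended on the pairs used, since against 79 higher and 46 lower genes, 0 lower genes were called with all 16 pairs, with the psoriasis pairs alone, with the pair as a random effect, without a block, or without psoriasis pair 26-27 or 41-42, 1 without psoriasis pair 29-30 and 2 without healthy pair 20-21. There were 2 higher genes with all 16 pairs, 8 with the psoriasis pairs alone and 0 with the pair as a random effect or without a block. The balance of directions turned with the filter, with 87 higher and 182 lower at a mean of at least 10 CPM, and over both donor groups 116 higher and 215 lower against 135 and 62. DESeq2 called 455 higher and 261 lower genes in psoriasis donors. Reads of HSPA6 and AKR1C3 may be shared with close paralogs. IL17A was at 0.08 (SE 0.19) in healthy and 0.53 (SE 0.26) in psoriasis donors, and ASL at -0.01 (SE 0.10) and -0.10 (SE 0.11), and neither gene passed. In psoriasis donors FOXP3 was at 0.26 (SE 0.09), IL4 at 0.13 (SE 0.17) and IL5 at 0.06 (SE 0.35), of the opposite sign to the fit of all 32 libraries, as was IL17A, and IL13 was at -0.15 (SE 0.13), and none of these passed. TH17 genes had a median of 0.14 in psoriasis donors with 16 of 21 positive (adjusted p = 0.00131), lost at adjusted p = 0.247 with an estimated correlation. Cell cycle genes had a median of -0.22 with 26 of 35 negative (adjusted p = 0.00131), lost at adjusted p = 0.0665 with an estimated correlation. B cell markers had a median of -0.18 (adjusted p = 0.0491), lost at 0.247 with an estimated correlation.

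The 4 libraries unlike the library with the neighbouring number, psoriasis replicates 35, 36, 38 and 39, were examined for 4 explanations. For 2 of the 4, vehicle replicate 38 and NR replicate 36, wrong labels may explain the mismatch. These 2 correlated with each other across numbers at 0.865, within the range of matching pairs, which began at 0.706. For the remaining 2 the best correlation with any library of the other treatment in the psoriasis group was 0.209, which leaves open whether a label is wrong. Healthy libraries were not searched for a match. Low depth was not borne out, as the lowest of the 4 held 12.8 M counts and all 4 were above 8.86 M, the lowest total among matching libraries. Monocyte content was not borne out either, since with the monocyte score removed the correlation was 0.127, against at least 0.529 in matching pairs.

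The mean NR change of NRF2 targets was positive in 14 of 14 matching pairs, with an exact sign-flip p of 0.0078 in healthy, 0.0313 in psoriasis and 0.000122 in all pairs. The 2 libraries that correlated at 0.865 across numbers, psoriasis vehicle 38 and NR 36, are not among these pairs. Their NRF2 scores were 4.28 and 4.33. In log2 CPM, HMOX1 was at 5.17 and 5.08, NQO1 at 1.76 and 1.49, GCLM at 4.62 and 4.71 and TXNRD1 at 7.52 and 7.53. They thus showed little of the rise seen in the pairs, and whether they share a donor is not known. The mean NRF2 change was 0.349 ± 0.083 in the 6 matching psoriasis pairs and 0.230 ± 0.116 in the 8 healthy pairs, a difference of 0.118. Chance may explain this difference (exact p = 0.0559 over 3003 splits). With 1 slope for both donor groups, adjustment for depth left 0.104 (SE 0.0444) and adjustment for monocyte content 0.119 (SE 0.0565), so neither removed the difference. The relation to monocyte content had opposite signs in the donor groups, as given below. A shared slope therefore cannot decide whether monocyte content plays a part. The NRF2 change itself went with the depth difference within a pair, with r = -0.613 over 14 pairs (permutation p = 0.0205), -0.206 without 2 of them, and rho = -0.437 (permutation p = 0.119). Within healthy pairs r was -0.772 and within psoriasis pairs -0.323. Within psoriasis pairs the NRF2 change followed the monocyte score with r = 0.928 (exact p = 0.0389) and rho = 0.829 (exact p = 0.0583), and r was -0.310 in healthy pairs (exact p = 0.454).

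For the lower RPL37P2 in psoriasis donors, a lower level of the parent gene RPL37 was not borne out, since RPL37 itself was at -0.081 (SE 0.105) in vehicle cells. That value cannot tell whether the share of RPL37 reads counted at the pseudogene differed, so shared reads are left open. A shift of ribosomal protein pseudogenes as a class could be part of the lower RPL37P2. Their median in vehicle cells was -0.423, with 387 of 445 negative and 119 lower against 2 higher at an unadjusted p under 0.05, but the exact p over splits of the libraries was 0.0852, which leaves this open. In NR cells the median was -0.232 with 368 of 454 negative (exact p = 0.433). Ribosomal protein genes had a median of -0.026 in vehicle cells.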
